A study of Mus musculus with 2 samples.

How the data were processed

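DNase-seq maps open chromatin: DNase I cuts DNA where it is not wrapped or covered by protein, and the cut ends are sequenced. Per the labels, the libraries came from the gastrocnemius of female B6CASTF1/J mice (an F1 cross of C57BL/6J with CAST) at 14 days of age, and the project is ENCODE. The 2 libraries were biological replicates of 1 group. They came from separate biosamples that carry the same donor record. The label of replicate 2 names a pair of sequencing instruments, and the label of replicate 1 names none, so a sequencing batch and the replicate cannot be told apart.

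For each library the deposited files comprised a strict peak list, a permissive peak list, a footprint list and a per-base file of false discovery rates, all on mm10, and replicates were not pooled per the labels of the files. The aligner, the peak caller, the footprint caller and their versions are not given in the sources used here. The deposited peak signal is the authors' own value per peak. Within a library every signal was a whole multiple of 1 fixed step (100% of values, within 0.05 of a step), with 142 steps per signal unit in replicate 1 and 150 in replicate 2. The scaling behind the signal is not stated, so ratios between replicates were centred on the median of all shared sites. The deposited per-base files hold q-values (false discovery rates) of the local cut rate, listed only where below 0.05. By these values the smallest false discovery rate inside a strict peak was at most 0.000997 in replicate 1 and 0.000998 in replicate 2, and inside a permissive peak at most 0.0500 in both. The deposited footprint lists give 1 level for every footprint, a false discovery rate of 0.01, and no score. Read totals are not given in the sources used here, so intervals on shares cover counting error over peaks, windows or genes only.

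The strict list was the main list and the permissive list an alternative. Sites shared by both replicates were made by merging peaks that overlapped by at least 1 bp and keeping merged sites that held a peak of each replicate. Chance overlap was measured with 100 circular shifts of a replicate's peaks within each chromosome. Positions were compared with the mm10 (GRCm38) reference genome and its gene annotation with 21911 protein-coding genes. A promoter site had its midpoint within 1000 bp of a protein-coding transcription start site (TSS), the promoter signal of a gene in a replicate was that of the strongest such peak (which may differ between replicates), and a distal site lay farther from every such TSS and was assigned to the nearest TSS within 50 kb. Coordinates are 1-based on mm10.

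Before the data were examined, 29 gene lists (13 of muscle genes and 16 of other cell types and controls, together 418 genes of the annotation, with 2 listed symbols absent from it), 25 consensus motifs, the tests and the alternatives were fixed. The rule for naming genes was fixed then too: of each list the 3 genes with the highest mean promoter signal, the 2 with most shared distal sites and up to 3 with no promoter peak in either replicate, a fixed set of muscle and control genes, the 10 protein-coding genes with the highest promoter signal and the 10 with most distal sites, and the 10 strongest distal sites. Xist, in the fixed set, is not protein-coding and has no value here. Lists were compared with all other protein-coding genes by Fisher's exact test for a shared promoter site. The median number of distal sites per gene was ranked among 10000 random lists matched in 10 bins on the length of the assignment territory. Random lists and sets left out the members of the list or set compared, and a permutation p-value below is a rank among them. Only in the comparison of fast with slow genes were list labels themselves permuted. Motifs were sought as exact matches on either strand in 150 bp around the midpoint of distal sites, against windows 1000 bp to each side that overlapped no permissive peak (Fisher's exact test). For footprints, the share of motif matches in strict peaks that overlapped a footprint was compared with that of 10 base-permuted versions of the consensus. All tests were two-sided, with Benjamini-Hochberg adjustment within each family and a threshold of 0.05. These tests compare genes, windows or matches within these 2 libraries, which are not independent replicates of a tissue. Shares carry Wilson 95% intervals, and ratios of shares carry 95% intervals on the log scale.

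The fixed alternatives were the permissive list, the stronger 50% of peaks, 50% reciprocal overlap, equal numbers of peaks, promoter windows of 500 and 2500 bp, TSSs of all annotated genes, assignment within 20 and 100 kb, random lists matched on promoter GC content or not matched on territory, GC-matched control windows (drawn with replacement, so that their p-values are too small), permuted consensus motifs, windows of 200 bp, footprints of both replicates, whole matches inside footprints, and each replicate alone. Leaving repeat bases out of the motif windows was chosen after seeing the data, as were the comparison of replicate ratios by motif and by gene list (against random sets of distal sites matched on GC content and mean signal, or of genes matched on the number of sites), the promoter, distal and muscle-gene comparison of motifs, the counts of 6-base sequences and the search for copies of Y peaks. With 1 group, no comparison between groups was made.

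The overlap of peaks, the gene lists by promoters and by distal sites, motifs in distal sites against flanking windows, motifs in footprints and the replicate ratios of sets of sites were tested on simulated data, and the other steps were not. For promoters of 21911 genes, 39.0% of 100 simulated lists of raised genes were recovered, and 0% of 100 unchanged lists were called. For distal sites, 57.0% of lists with 2 added sites per gene and 100% of lists with 5 were recovered, with 0% of unchanged lists called. For motifs in 20000 windows, 100% of motifs planted in 2% of the windows were recovered and 0% of the others called. Several real motifs were rarer, such as MEF2 in 0.550% of distal sites. Simulated sites and controls had the same base composition, so these shares do not cover a difference in GC content. In the footprint comparison with 2000 matches per motif these shares were 100% and 5.00%, and for replicate ratios over 40000 sites they were 100% and 0%. The tools were python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, matplotlib 3.10.9, bedtools 2.31.1 and blastn 2.17.0.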

Results

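Open chromatin was mapped by DNase-seq in the gastrocnemius, the large calf muscle, of 14-day-old female mice, in 1 group of 2 biological replicates. Replicate 1 had 87558 strict peaks covering 15.7 Mb, with a median width of 179 bp. Replicate 2 had 79562 strict peaks covering 14.5 Mb, with a median width of 180 bp. The median peak signal, the authors' value per peak, was 1.53 in each replicate, which is 216 whole signal steps in replicate 1 and 230 in replicate 2. The permissive lists held 142031 and 133321 peaks. Read totals are not given in the sources used here, and the peak counts and signal steps are the available measures of depth.

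The first comparison was between the replicates, which were mostly open at the same places. Of the peaks of replicate 1, 78.9% (95% interval 78.6 to 79.2%) overlapped a peak of replicate 2, and 86.9% (86.7 to 87.1%) of the peaks of replicate 2 overlapped a peak of replicate 1. Circularly shifted peaks overlapped in 1.14% and 1.25% of cases on average. Merging gave 68349 shared sites covering 14.4 Mb. Across these sites the signals of the replicates had a Spearman correlation of 0.961 and a Pearson correlation of 0.974 on the log2 scale, where sites are not independent replicates. The log2 ratio of replicate 2 to replicate 1 had a median of -0.14 and an SD of 0.30, and 99.4% of sites differed by less than 2-fold. Peaks of a single replicate were weak: the 18484 found in replicate 1 alone had a median signal of 0.784 against 1.95 for its shared peaks, and the 10428 found in replicate 2 alone had 0.665 against 1.76. In the permissive list of the other replicate, 68.2% of the former and 52.8% of the latter were present. With 1 library on each side, no test of a difference between replicates was possible.

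Ratios between the replicates at distal sites were also set out by motif, chosen after values were seen, with 1 library on each side and so with no test between replicates. Centred on the median of all shared sites, the log2 ratio of replicate 2 to replicate 1 had medians from -0.13 (EBF, 490 sites) to 0.07 (CTCF, 3952 sites) among fixed motifs with at least 50 sites, and -0.09 at the 1917 sites with the glucocorticoid and androgen response element ACANNNTGT. A longer form of this element, the palindrome GNACANNNTGTNC, was chosen after values were seen. Its 266 sites had a median of -0.47, outside the -0.10 to 0.06 spanned by 10000 random sets matched on GC content and signal. Several fixed motifs also left the range of their own 1000 matched sets, by less. Among them were CTCF (range -0.07 to -0.04), EBF (-0.05 to 0.05), ACANNNTGT (-0.04 to 0.02) and AP-1 (median -0.05, range -0.03 to 0.01), and TEAD and CAGCTG lay just outside. A shift between replicates was thus not limited to the palindrome.

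**Figure D1:**
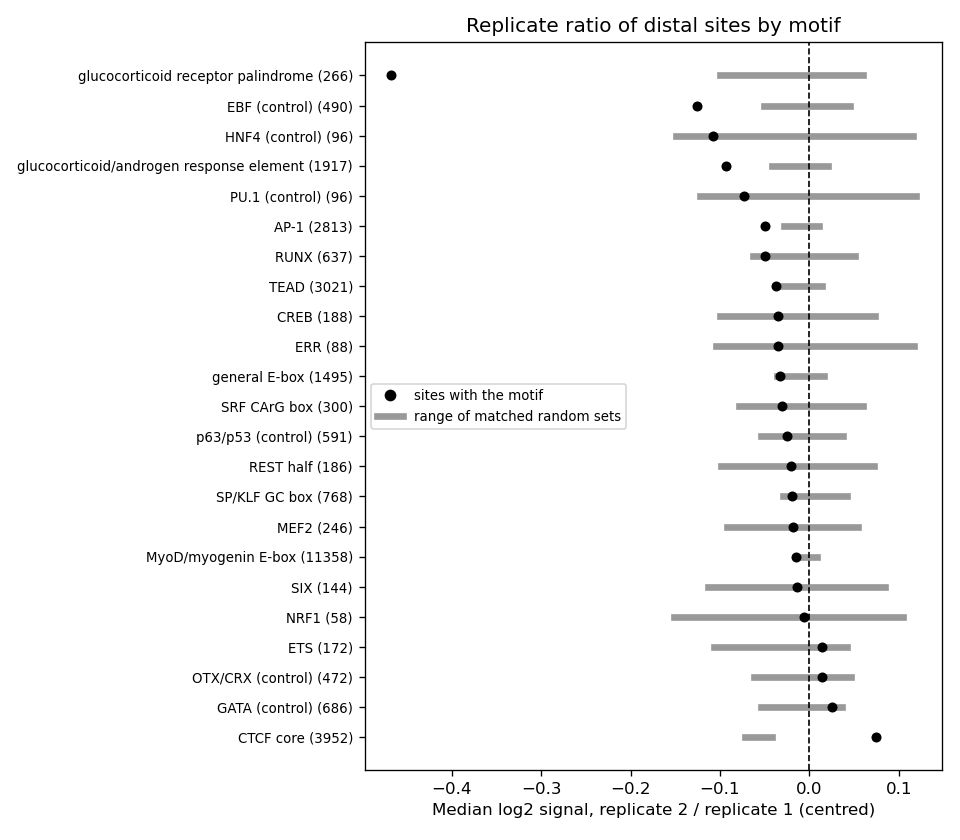
Median centred log2 ratio of replicate 2 to replicate 1 at distal sites with each motif (points; number of sites in brackets) and the range of matched random sets (bars). Sites with the glucocorticoid receptor palindrome lie farthest to the left, at -0.47.

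The next question was where in the genome the muscle was open. Promoters held 31.4% of the peaks of replicate 1 and 33.9% of those of replicate 2 (mean 32.7% ± 1.76, SD, n = 2), while windows of 1000 bp around protein-coding TSSs make up 3.70% of the genome. This was 8.49 and 9.16 times the genome share. Introns held 29.6% and 28.5% of peaks, intergenic DNA 34.9% and 33.3%, and exons 4.12% and 4.33%. Of 21911 protein-coding genes, 13959 (63.7%) had a shared promoter site. There were 44700 shared distal sites, 65.4% of all shared sites, and 32509 of them lay within 50 kb of a protein-coding TSS.

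The 10 genes with the strongest promoters were named by rule. The highest mean signal was at the site shared by Hjurp, which encodes a centromere chaperone, and its divergent neighbour Trpm8, with 65.2 in replicate 1 and 55.2 in replicate 2. Next came a site just upstream of Mplkip and inside Sugct, which overlaps it (60.0 and 48.2), Dynlt1b, a dynein light chain gene (57.2 and 48.4), Bahcc1 (54.6 and 46.8) and the aspartyl aminopeptidase gene Dnpep (50.5 and 37.5). The remaining 3 sites were those of Fzr1, an activator of the anaphase-promoting complex (47.4 and 38.1), the splicing gene Snrnp70 (48.1 and 36.8) and the nuclear pore gene Nup107 (44.7 and 38.1). Since Hjurp and Trpm8, and Mplkip and Sugct, share 1 site each, the signal cannot be assigned to either gene of a pair.

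The gene lists asked which programmes of muscle and of its other cell types had open promoters. In the main test, lists of the membrane scaffold, the energy supply, the clock and the transcription factors of muscle lay above other genes. The housekeeping control list did so too, and only 2 of these 6 calls were kept against GC-matched lists. All 12 genes of the dystrophin-glycoprotein complex, which ties the fibre's cytoskeleton to the matrix around it, had a shared promoter site (Fisher's exact test, adjusted p = 0.0149), as did 27 of 28 mitochondrial and fatty-acid oxidation genes (adjusted p = 6.5e-04), 18 of 19 glycolysis and glycogen genes (adjusted p = 0.0105) and all 16 circadian clock genes (adjusted p = 0.00504). Of the myogenic transcription factors and cofactors, 17 of 19 had one (Fisher's exact test, adjusted p = 0.0416), and of the housekeeping control genes 15 of 15 (adjusted p = 0.00767). Each share exceeded the 63.7% of other genes by Fisher's exact test over 29 lists with Benjamini-Hochberg adjustment. In the dystrophin complex, Dag1, which encodes dystroglycan, had a signal of 32.3 in replicate 1 and 28.7 in replicate 2. Esrra, a nuclear receptor gene for mitochondrial programmes, had 37.0 and 31.5, and Gys1, muscle glycogen synthase, 35.8 and 28.4. The clock genes had the highest list medians, 18.1 and 13.9, led by Tef (46.1 and 35.3), Nr1d2 (26.6 and 20.7) and Nr1d1 (25.4 and 19.7). Against random lists matched on promoter GC content, the dystrophin complex (permutation against these lists, adjusted p = 0.00290) and the mitochondrial list (adjusted p = 0.00911) still passed, while glycolysis (0.0744), clock (0.162), myogenic factors (0.261) and housekeeping genes (0.175) did not. The call of the myogenic factors also ended without replicate 1 (Fisher's exact test, adjusted p = 0.0584), with a promoter window of 2500 bp (0.0920) and in the stronger 50% of sites (0.780).

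Contractile and signalling genes of the fibre did not pass the test at promoters, though most members were open. Shared promoter sites were present at 15 of 18 sarcomere, Z-disc and M-band genes (Fisher's exact test, adjusted p = 0.158), 13 of 15 excitation-contraction coupling genes (adjusted p = 0.158), 13 of 15 atrophy and proteostasis genes (adjusted p = 0.158) and 11 of 12 neuromuscular junction genes (adjusted p = 0.129). The fast-fibre list had 12 of 15 (Fisher's exact test, adjusted p = 0.373), the slow-fibre list 9 of 14, the developmental list 7 of 10 and the limb-position list 12 of 18 (adjusted p = 1 for these 3). Myom1, an M-band protein gene, had 27.0 in replicate 1 and 23.0 in replicate 2, Cryab, a small heat-shock protein gene, 15.5 and 11.95, and Bin1, which shapes transverse tubules, 14.1 and 12.2. Skeletal actin Acta1 had 9.23 and 6.68, desmin Des 10.1 and 8.80, titin Ttn 3.49 and 3.19, and the muscle creatine kinase gene Ckm 13.1 and 8.99. Chrna1, the acetylcholine receptor subunit of the synapse, had 1.64 and 1.27. Among limb genes, Hoxc10 had 13.5 and 14.0, and the hindlimb genes Pitx1 and Tbx4 had 0.919 and 1.28, and 1.99 and 1.56. The forelimb gene Tbx5 had no strict promoter peak in either replicate.

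**Figure D2:**
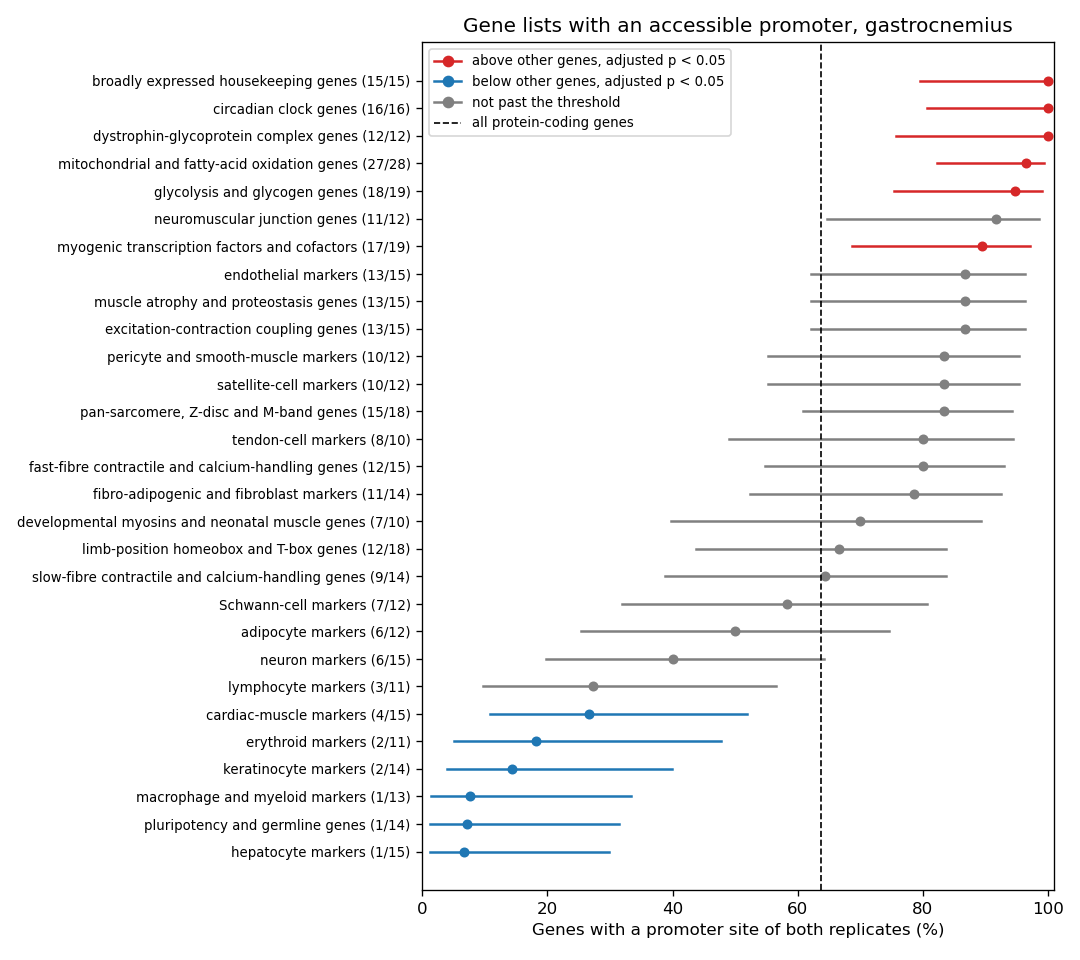
Share of the genes of each list with a promoter site of both replicates (points, %, with the number of genes in brackets) and its Wilson 95% interval (lines), with the share of all protein-coding genes as a dashed line. The lists past the threshold above other genes range from 17 of 19 to all members, and those below it range from 1 of 15 to 4 of 15.

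The lists of other cell types asked which neighbours of the fibres were visible. For cells that sit in and around muscle, shared promoter sites were present at 13 of 15 endothelial markers (Fisher's exact test, adjusted p = 0.158), 10 of 12 satellite-cell markers (0.320), 10 of 12 pericyte and smooth-muscle markers (0.320), 11 of 14 fibro-adipogenic and fibroblast markers (0.469), 8 of 10 tendon-cell markers (0.436), 7 of 12 Schwann-cell markers (0.855) and 6 of 12 adipocyte markers (0.450), none of them past the threshold. The satellite-cell gene Cdh15, an M-cadherin gene, had 5.83 in replicate 1 and 6.02 in replicate 2, and the endothelial genes Vwf and Pecam1 had 9.09 and 8.02, and 0.841 and 0.744. Col1a1, a fibroblast collagen gene, had 8.16 and 9.35. For blood and distant lineages, fewer promoters had a shared strict site. One was present at 1 of 13 macrophage and myeloid markers (Fisher's exact test, adjusted p = 4.3e-04), 2 of 11 erythroid markers (0.00988), 4 of 15 cardiac markers (0.0147), 1 of 15 hepatocyte markers (2.0e-04), 2 of 14 keratinocyte markers (0.00122) and 1 of 14 pluripotency and germline genes (2.5e-04), each below other genes. Lymphocyte markers (3 of 11, Fisher's exact test, adjusted p = 0.0503) and neuron markers (6 of 15, adjusted p = 0.129) did not pass. Csf1r, the receptor of macrophage growth factor, albumin Alb, the cardiac myosin Myh6 and the pluripotency gene Pou5f1 had no strict promoter peak in either replicate. In the permissive list Pou5f1 had peaks of 0.678 and 0.718, and Csf1r 1 of 0.592 in replicate 2. Under the permissive lists the macrophage list (Fisher's exact test, adjusted p = 0.192) and the cardiac list (0.353) no longer passed, and the cardiac list also failed with a promoter window of 2500 bp (0.0920) and without replicate 2 (0.238).

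Distal sites were counted per gene for the same lists, and the difference between promoter and distal results was not tested. Sarcomere genes had a median of 4 shared distal sites per gene against a random median of 1 (permutation against random lists, adjusted p = 0.00580), excitation-contraction coupling genes 4 against 1 (adjusted p = 0.00773), fast-fibre genes 2 against 0 (adjusted p = 0.0329), developmental genes 3 against 0.50 (adjusted p = 0.0423), atrophy genes 3 against 1 and clock genes 3 against 0.50 (adjusted p = 0.0209 for both). Satellite-cell markers had 4.5 against 1 (permutation, adjusted p = 0.00773). No other list of the 29 passed against 10000 random lists matched on territory. The random median was at most 1 for every list, and a list with a random median of 0 could not fall below chance. Slow-fibre genes (median 2, permutation, adjusted p = 0.0677), fibroblast markers (3.5, adjusted p = 0.0544) and myogenic factors (3, adjusted p = 0.333) did not pass. Bin1 had 21 distal sites, Dysf, whose product reseals the membrane, 17, Dlk1, an imprinted growth gene, 13, Foxo1, a transcription factor gene of atrophy, 10, and the clock activator Arntl 11. In the stronger 50% of sites the calls of the fast-fibre (permutation, adjusted p = 0.148), developmental (0.330) and sarcomere lists (0.241) ended and the median of the atrophy list turned to -0.07 sites from the mean of the random medians. The developmental call also ended with assignment within 20 kb (permutation, adjusted p = 0.0715), and it (0.0594) and the fast-fibre call (0.233) ended against random lists not matched on territory. Without replicate 2 the fast-fibre call ended too (permutation, adjusted p = 0.0514), and the number of lists above chance rose from 7 to 13.

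Single loci showed how these sites lay. Myod1, the master regulator of muscle fate on chromosome 7, had a promoter site at 46376261 to 46376500 with a signal of 6.54 in replicate 1 and 6.10 in replicate 2, and 10 distal sites. The 3 strongest upstream, all intergenic, lay 26.2 kb away at 46350201 to 46350420 (4.26 and 4.23), 34.8 kb away at 46341541 to 46341820 (3.94 and 3.22) and 23.0 kb away at 46353301 to 46353560 (3.34 and 2.75). A site 2.75 kb downstream of the TSS, at 46379141 to 46379300, had 5.00 and 4.59. It holds the E-box CAGCTG, as do the upstream sites 34.8 kb and 23.0 kb away. The related factors were weaker: Myog had promoter sites with 1.59 and 1.79 at 134289651 to 134289960 on chromosome 1 and with 1.85 and 1.24 at 134290407 to 134290643, Myf5 had a promoter signal of 0.883 and 0.711, and Myf6 of 0.975 and 0.864. Pax7, the marker of satellite cells, had a strict promoter peak in replicate 1 alone (1.59, with 1.21 in the permissive list of replicate 2) and 6 distal sites, the strongest 25.3 kb upstream on chromosome 4 at 139858761 to 139858940 (4.80 and 5.66). Pax3 had no strict promoter peak in either replicate and no distal site. Upstream of Des, 4 intergenic sites lay between 15.2 and 17.3 kb from the TSS on chromosome 1, the strongest at 75344321 to 75344540 (4.36 and 3.25). At Chrna1 the strongest site was 4.43 kb upstream on chromosome 2, at 73584681 to 73584860 (5.07 and 4.44).

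In the myosin heavy chain cluster on chromosome 11, most shared sites lay in the stretch between Myh3 and Myh2. Myh3, Myh2, Myh1 and Myh4, which encode the embryonic and the fast adult myosins, had no strict promoter peak in either replicate, and Myh8, the neonatal myosin, had 0.982 in replicate 1 and 1.08 in replicate 2. In the permissive lists Myh1 had 0.516 and 0.532, and Myh4 had 1.010 in replicate 1 alone. Yet 11 shared distal sites were nearest to Myh3 and 6 to Myh2. The strongest of them lay between these genes, at 67120781 to 67121040 (5.22 and 4.51) and at 67112101 to 67112300 (4.22 and 2.90, with 2 CAGCTG matches). The slow myosin Myh7 on chromosome 14 had no promoter peak and 1 distal site.

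**Figure D3:**
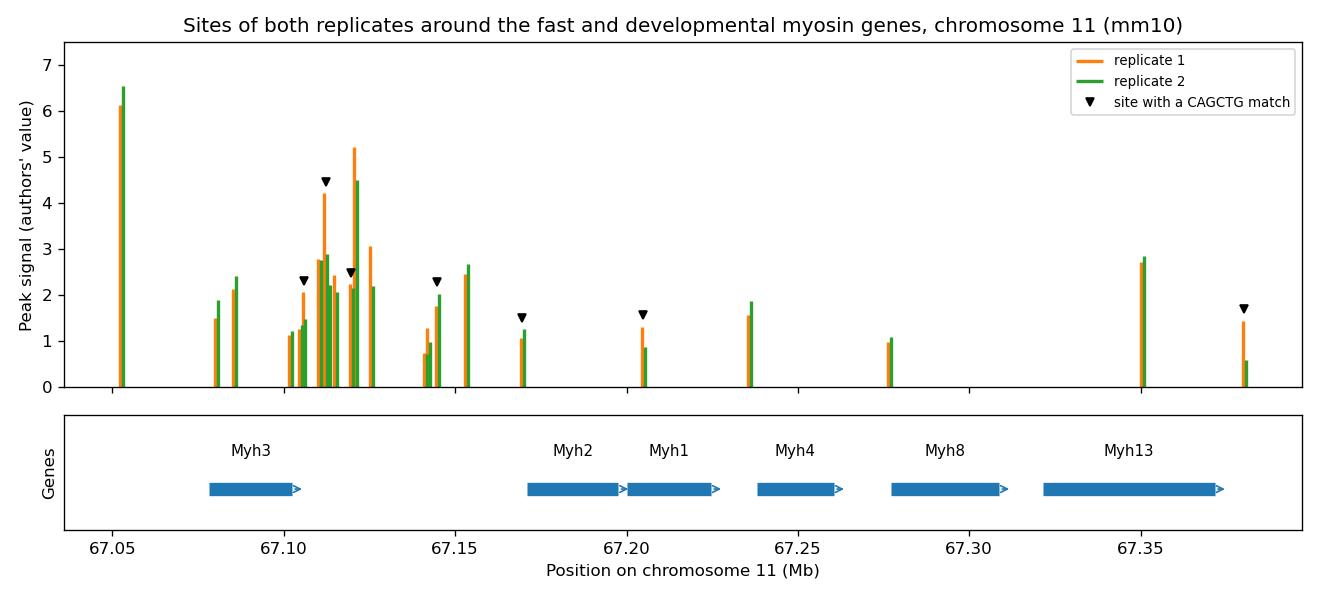
Signal of the sites of both replicates along the cluster of fast and developmental myosin genes on chromosome 11 (x axis, Mb; y axis, the authors' peak signal; orange, replicate 1; green, replicate 2), with triangles at sites that hold CAGCTG and the genes as bars. The sites are densest between Myh3 and Myh2, and the strongest there reaches 5.22 in replicate 1.

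Gastrocnemius is a mixed muscle with mostly fast fibres, and the promoters of fast and slow genes were compared by their mean signal. The fast list was led by Tpm1 (23.2 in replicate 1 and 19.8 in replicate 2), Mylpf (11.7 and 10.1) and Actn3 (10.05 and 10.004), and the slow list by Myl6b (15.6 and 13.3), Tpm3 (12.2 and 10.2) and Atp2a2 (9.20 and 8.87). On the scale of log2(mean signal + 0.0399), fast genes had a mean of 0.98 ± 3.06 (SD, n = 15) and slow genes of -0.10 ± 3.20 (SD, n = 14). The difference of 1.08 was smaller than the spread within each list (permutation test with 100000 resamples, two-sided p = 0.355). Several leading members, such as Tpm1, Tpm3 and Atp2a2, are used in many cell types.

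Distal sites were compared with DNA 1000 bp to each side to find which binding motifs they carried. Of 44700 distal sites, 25.4% (25.01 to 25.82%) held the E-box CAGCTG, the site preferred by MyoD and myogenin, against 7.03% of 81805 flanking windows, a ratio of 3.61 (3.51 to 3.72). The core of CTCF, an insulator protein, was found in 8.84% of sites against 0.0599% of windows, a ratio of 148 (111 to 196). MEF2, the partner of the myogenic factors (CTAWWWWTAG), was 2.11 times as frequent (1.76 to 2.54), the MEF3 motif (TCAGGTTTC) 1.86 times, TEAD 1.26 times and AP-1 2.48 times. Motifs of ubiquitous activators were raised too, with ratios of 5.05 for NRF1, 4.99 for CREB, 3.81 for the SP/KLF box and 2.89 for ETS. The NFI palindrome had 48 sites against 3 windows, a ratio of 29.3 with an interval of 9.12 to 94.0. The REST motif part (2.99), the general E-box CACGTG (1.53) and, among controls, EBF (3.21) and PU.1 (1.67) were raised as well. Fewer matches than in flanking windows were found for ERR (0.413), the control GATA (0.475), RUNX (0.882) and the glucocorticoid and androgen response element ACANNNTGT (0.919). Without replicate 2 only 2 of these 4 calls were kept: RUNX no longer passed and the response element reversed. By Fisher's exact test over 25 motifs, 15 passed above (largest adjusted p = 5.4e-04) and 4 below (largest adjusted p = 0.0115). The SRF box (0.887), HNF4, p63/p53, OTX/CRX and HNF1 (1 site against 9 windows) did not pass, and the SOX-OCT motif matched 1 site and 0 windows. Sites had a GC content of 54.8% against 45.7% in flanking windows: against GC-matched windows the CAGCTG ratio was 2.31, that of CTCF 70.6 and that of MEF2 5.02, while RUNX (1.21) and the response element (1.18) turned to above. Against permuted versions of the same consensus, the general E-box (0.424) and ETS (0.718) turned to below, CREB no longer passed (Fisher's exact test, adjusted p = 0.288), and ERR (3.03), RUNX (1.77) and the response element (1.42) to above.

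**Figure D4:**
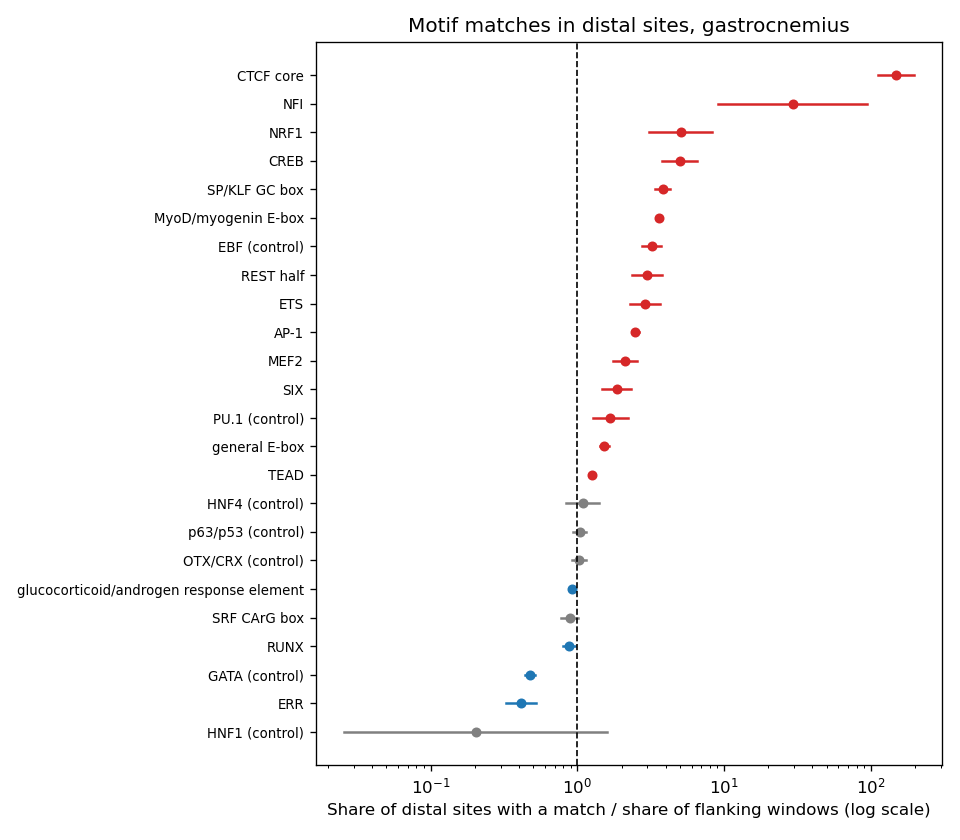
Ratio of the share of distal sites with a motif match to the share of flanking windows (points; x axis, log scale) with 95% intervals (lines), for motifs with a match in at least 1 flanking window. Intervals wholly above 1 are red and wholly below 1 blue, and CTCF (148) and NFI (29.3) lie farthest to the right.

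Motifs also differed between kinds of sites, in comparisons chosen after values were seen. Promoter sites (23649) carried more ETS motifs than distal sites (3.97% against 0.385%, Fisher's exact test, adjusted p = 2.4e-262), more SP/KLF boxes (13.3% against 1.72%) and more NRF1 motifs (1.19% against 0.130%, adjusted p = 4.5e-75). They carried fewer CAGCTG E-boxes (12.1% against 25.4%) and fewer CTCF cores (1.64% against 8.84%). Among the 677 distal sites nearest to 211 genes of the 13 fixed muscle lists, 1.77% held the MEF2 motif against 0.537% of other assigned distal sites, a ratio of 3.30 resting on 12 sites (Fisher's exact test, adjusted p = 0.0122 over 25 motifs). With the glycolysis, mitochondrial, clock and limb-position lists counted among the others, a grouping also chosen after values were seen, it was 2.04% of 490 sites against 0.540%, a ratio of 3.78 on 10 sites (Fisher's exact test, adjusted p = 0.0123). CAGCTG was as frequent near genes of the 13 lists as elsewhere (24.7% in both, Fisher's exact test, adjusted p = 1), and no other motif passed.

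Footprints, short stretches protected from cutting inside open sites, showed which motifs were covered. Replicate 1 had 338694 footprints with a median width of 11 bp, 70.1% of them in strict peaks, and replicate 2 had 301069 with a median width of 10 bp, 69.1% of them in strict peaks. Of these, 56.0% of replicate 1 and 64.9% of replicate 2 overlapped a footprint of the other replicate, against 28.1% and 31.8% after moving footprints by 20 to 40 bp. Nearly every CTCF match in a peak was covered (98.1% in replicate 1 and 97.1% in replicate 2, against 44.6% and 45.9% of permuted motifs), and the same held for NRF1 (96.8% and 96.5%) and NFI (98.8% and 97.0%). CREB matches were covered in 85.7% and 84.9% of cases against 33.1% and 31.1%, and ETS matches in 57.8% and 58.3% against 34.3% and 31.7%. The muscle motifs rose less far above their permuted versions than the motifs just named: MEF2 was covered in 35.7% and 33.0% of cases against 21.2% and 19.0%, and CAGCTG in 33.2% and 32.2% against 27.6% and 25.7%. The SP/KLF box (80.2% and 75.5% against 71.1% and 64.8%) rose less than MEF2. The control EBF (75.6% and 66.1% against 39.5% and 37.2%) rose more. By Fisher's exact test over 25 motifs, 15 motifs passed above in replicate 1 (largest adjusted p = 0.00688) and 14 in replicate 2 (largest adjusted p = 8.7e-04). Below their permuted versions lay p63/p53 and the response element in both replicates and GATA in replicate 1. Where the whole match had to lie inside the footprint, TEAD, AP-1 and OTX/CRX turned to below in both replicates and MEF2 in replicate 1, and DNase I cuts some sequences more readily than others, which this comparison does not remove.

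The 10 strongest distal sites were named by rule. The strongest lay in an intron of Mid1 on chromosome X, at 169998241 to 169998400 (46.8 in replicate 1 and 35.0 in replicate 2). Others were intergenic, such as that 13.7 kb from Cct8l1 on chromosome 5 at 25529581 to 25529860 (44.3 and 34.9). On chromosome 8, an intergenic site lay at 20424741 to 20424920, 61.6 kb from the nearest TSS, that of Gm15319 (41.1 and 34.0). Another lay at 20122145 to 20122300, 219 kb from that of Gm31371 (35.3 and 30.7). An intron of the clock gene Per1 on chromosome 11 held a site at 69097021 to 69097240 (35.1 and 27.2). The rest lay in exons of Cers5 (31.8 and 34.1) and Lars2 (25.6 and 34.2), 1.29 kb from a TSS of Bahcc1 (33.9 and 25.6), in an intron of Gm42906 (33.7 and 25.1) and 14.5 kb from Zfp395 (31.2 and 26.9). Repeated or multi-copy regions were not filtered out of the deposited peaks here. Whether such sequence contributed to the signal of these sites was not tested. Of all genes, Sik1, a salt-inducible kinase gene, had the most distal sites (54 within 98.4 kb), and others with many were Gse1 (33), Sh3pxd2a (33), the adhesion gene Tns1 (31), Nav2 (28), Nfic (27), Arhgap26 (26), Sept9 (26) and Frmd4a (24). The sites of Sik1 had a median signal of 0.351.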

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

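Of the tests in this part, those on single-copy Y genes and on Y peaks at the end of the chromosome and elsewhere were chosen only after the result was seen. Both libraries are labelled female, yet 10 strict peaks of replicate 1 and 21 of replicate 2 lay on chromosome Y, a chromosome that female cells lack and that no comparison was about. These are numbers of called peaks, some of them overlapping, and give no amount of Y signal. Male cells or a male sample were argued against: the promoters of Kdm5d, Eif2s3y, Uty and Ddx3y held 0 peaks of the permissive list in either library, while all 4 X homologues had promoter peaks in both, such as Kdm5c (22.8 in replicate 1 and 15.9 in replicate 2) and Kdm6a (39.2 and 30.5). Copies elsewhere in the genome, defined as matches outside Y at 95% identity over 80% of the length, were found for 45.2% of the Y peaks (14 of 31, 7 with a match on chromosome X), which leaves the whole set undecided. They may account for the peaks before 90 Mb, of which 100% (12 of 12) matched. Of the peaks beyond it 10.5% (2 of 19) matched, which argued against copies of that length on the other assembled chromosomes. Shorter matches were not counted, and sequence outside the assembled chromosomes was not searched, so copies of those kinds stay open. For the peaks beyond 90 Mb a CAST variant near the pseudoautosomal border stays open too and was not tested, and with 1 group no biological explanation was tested.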

How the results depend on the processing

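Leaving repeat bases out of motif windows was chosen after seeing the data, and it changed 1 of 25 motif calls, that of SRF, which became lower than in flanking windows. Over all alternatives, 632 values kept their call, stayed without one in either direction, or had no test and were not counted as moved. Another 17 reversed, 28 no longer passed, 51 newly passed and 30 without a test moved. The fast minus slow difference never passed: it ranged from 0.79 to 1.35 on the log2 scale (p from 0.189 to 0.487), and was 8.58 percentile points by ranks. The permissive lists gave 142031 and 133321 peaks, 74.5% and 79.5% of them shared, a Spearman correlation of 0.956, 24.9% at promoters, and 10 promoter lists and 12 distal lists above other genes. The stronger 50% of peaks (43791 and 39801) were shared in 97.6% and 98.9% of cases, with 44.8% at promoters, 4 distal lists above chance and a correlation of 0.946 among the stronger shared sites. The distal difference of the atrophy list reversed there to -0.0681. Shared peaks were 72.9% and 80.2% with 50% reciprocal overlap, and 83.4% and 83.5% with equal numbers of peaks. Promoters held 26.9% of peaks with a window of 500 bp, 39.6% with 2500 bp and 36.4% with TSSs of all annotated genes, as the construction of these settings implies. With random lists matched on GC content, 2 promoter lists lay above. Without replicate 1 the myogenic factors no longer passed at promoters (Fisher's exact test, adjusted p = 0.0584), and without replicate 2 neither did the cardiac list (0.238), the fast-fibre list at distal sites (permutation, 0.0514) or RUNX (0.271). Newly passing without replicate 2 were the sarcomere, neuromuscular junction and satellite-cell lists at promoters (Fisher's exact test, adjusted p = 0.0251 for each). At distal sites the glycolysis (0.0104 without replicate 1 and 0.0128 without replicate 2), limb-position (0.0135 and 0.0128) and fibroblast lists (0.0199 and 0.0108) newly passed without either replicate, and the slow-fibre (0.0128), neuromuscular junction (0.00967), myogenic (0.0370) and housekeeping lists (0.0258) without replicate 2. SRF matches became fewer than in flanks without either (0.00953 and 0.0479), as did HNF1 matches without replicate 2 (0.0371). With single replicates, 10 to 13 distal lists lay above, 13 of them with replicate 2 left out, and the log2 odds of the glucocorticoid and androgen response element ranged from -0.157 to 0.0264, reversing without replicate 2.

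Against GC-matched windows 2 motifs lay below, and the log2 odds of SRF (0.28), the response element (0.25) and RUNX (0.28) reversed. Against permuted consensus motifs those of the general E-box (-1.31), ETS (-0.48), ERR (1.60), the response element (0.53) and RUNX (0.83) reversed. Of the 15 motifs above flanking windows, 12 kept their call against permuted motifs, and all 15 kept it under the permissive lists, GC-matched windows, windows of 200 bp, single replicates and repeats left out. RUNX lost its call below with windows of 200 bp (Fisher's exact test, adjusted p = 0.0542), and CREB its call above against permuted motifs (0.288). With 50% reciprocal overlap, 44.3% and 49.9% of footprints were shared. Motifs below their permuted versions numbered 6 in replicate 1 with footprints of both replicates, where TEAD, HNF4 and OTX/CRX lost their calls above (12 of 15 kept), and 5 in replicate 1 and 6 in replicate 2 with whole matches inside. Whole matches reversed MEF2 (-0.41), TEAD (-0.18), AP-1 (-0.39) and OTX/CRX (-0.42) in replicate 1, and TEAD (-0.20), AP-1 (-0.13) and OTX/CRX (-0.51) in replicate 2. HNF4 in replicate 1 and MEF2 and the general E-box in replicate 2 lost their calls above there, and GATA in replicate 1 its call below. For all these changes the cause was not tested, except where the setting itself changes the number of peaks or the length of a window. The setting with the stronger 50% of footprints was not run, because the footprint lists give no score. No paired analysis was possible because there was 1 group. What depth limits was not tested, since read totals are not given in the sources used here. Peaks of a single replicate were weak, with median signals of 0.784 and 0.665.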

Other observations

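The palindrome of the glucocorticoid receptor, the test with repeat bases left out, and the values on single genes, 6-base sequences and chromosome 9 were chosen only after results were seen, and the test on glucocorticoid-responsive genes was revised after its first form was seen. Several muscle genes without a strict promoter peak in either replicate had distal sites of both replicates: Trdn, a gene of calcium release, had 5, the muscle sodium channel gene Scn4a 4 and Mstn, the gene of the growth inhibitor myostatin, 3. Of the 9 macrophage and myeloid markers with no strict promoter peak, 7 had a permissive one and 5 had shared distal sites, among them the mannose receptor gene Mrc1 with 4. Of the 14 hepatocyte markers with none, 1 had a permissive promoter peak and 5 had shared distal sites. All 7 neuron markers with none had shared distal sites, among them Gad1 and Neurod2 with 2 each.

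Among all 2080 sequences of 6 bases (each counted with its reverse complement), GGCGCC was raised most in distal sites over GC-matched flanks (2.94 times), followed by TGCCAA (2.70), GCGCCC (2.64) and CAGCTG (2.59). At the start of chromosome 9, the site at 3002461 to 3002621 had a signal of 43.9 in replicate 1 and 8.71 in replicate 2, a ratio of 5.04, and 4 further shared sites up to 3025940 had ratios of 3.54, 4.63, 3.21 and 1.21. Whether repeated sequence contributed to the signal of these sites was not tested.

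Distal sites with the glucocorticoid receptor palindrome GNACANNNTGTNC had lower signal in replicate 2: the median centred log2 ratio of 266 sites was -0.47, and 83.8% of them lay below 0 against 50.9% of all distal sites. GC content and signal strength were argued against as the cause, since 10000 matched sets spanned -0.10 to 0.06. Sites with EBF, AP-1 and some other fixed motifs also lay below their matched ranges, by less. CTCF sites went the other way, with a median of 0.07 above their matched range of -0.07 to -0.04. A lower signal in replicate 2 was thus not limited to this motif, and not all motifs shared it. A different hormone response or time of day may have contributed, if the replicates are separate animals, which their shared donor record leaves open: motif-free distal sites of 26 glucocorticoid-responsive genes (136 sites, median -0.11) lay at percentile 0.15 among 2000 random sets of genes matched on the number of sites (permutation p = 0.0040, not adjusted), though only 15 of the 26 genes lay below 0, and the 49 sites of endothelial markers, for which no such response was predicted, had a lower median of -0.13 (permutation p = 0.0230, adjusted 0.230). A first form of this test, seen before the second was set up to follow the wording of the prediction, used sets of sites and gave percentile 0.20, with a similar permutation p of 0.0050 that missed the threshold when adjusted over 30 lists (0.0750). In that form the 56 distal sites of the circadian clock genes, which bear on time of day, did not pass. Their median was -0.08, at percentile 13.45 (permutation p = 0.270, adjusted 0.799). All these p-values compare sites or genes within these 2 libraries, not replicates. The sequencing batch is confounded with the replicate and cannot be told apart from a difference between the biosamples, and no group of the design tests a biological explanation.

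Fewer ERR and GATA matches lay in distal sites than in flanking windows. Interspersed repeats in the flanks were argued against as the whole cause: with repeat bases left out, the ratio of match density was 0.598 (0.458 to 0.780) for ERR and 0.421 (0.385 to 0.459) for GATA. The ERR deficit was also there against GC-matched windows (log2 odds -1.14), while ERR matches were more frequent than those of its permuted consensus (log2 odds 1.60), so its direction depends on the kind of control. The GATA deficit kept its direction but was smaller against GC-matched windows, with a ratio of shares of 0.761 against 0.475 for flanking windows. Against its permuted consensus the GATA ratio was 0.602. No biological explanation was tested.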
